A study of Caenorhabditis elegans with 12 samples.

How the data were processed

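Gene expression was measured in Caenorhabditis elegans on Affymetrix arrays, from animals at the mid to late L4 stage, the last larval stage. The 12 arrays fall into 4 groups of 3: wildtype animals or hrg-2 mutants, each grown with 4 or 20 µM heme. C. elegans cannot make heme and takes it from its medium, so the concentration supplied sets its heme status. Per the labels' protocols, biotin-labelled cRNA was made from total RNA isolated with a column kit. The deposited values are log2 expression values, 1 per probe set and array, made by the authors with RMA (robust multi-array averaging, which subtracts background, normalizes between arrays and summarizes probes) in Partek 6.5, per the submitters' processing notes. The RMA settings, and whether any probe set was filtered out, are not given in the sources used here. The array medians of these deposited log2 values lay between 5.743 and 5.94. The number of arrays limits the precision of every value below. The labels do not say that the 3 arrays of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

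The deposited table holds 22625 probe sets. The 77 control probe sets were left out, and 22548 were tested. Gene names came from the platform annotation given for these probe sets, dated 2016, with symbols checked against the RefSeq annotation of the assembly WBcel235, which changed 0 symbols. One gene symbol was paired with 20810 probe sets, several symbols with 843 and none with 895. These cover 17138 genes, of which 2998 have more than 1 probe set. No gene was named from a probe set with several symbols. The annotation pairs 0 probe sets with hrg-2, so the genotype labels could not be checked against the mutated gene itself. No genome sequence was used, and no coordinates are given.

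The test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) on the deposited log2 values. A single model with 4 group means was fitted to all 12 arrays, with 8 residual degrees of freedom and 2.24 prior degrees of freedom. From it came the genotype difference (mutant minus wildtype) at 4 µM, at 20 µM and averaged over both, the difference between these genotype effects (20 µM minus 4 µM), and the heme difference (20 µM minus 4 µM) in each genotype. Every adjusted p printed for a gene or probe set is limma's, with Benjamini-Hochberg adjustment over the 22548 probe sets and a threshold of 0.05. Errors of differences are standard errors (SE) from the moderated fit, errors of group means are SDs with n = 3, and folds are powers of 2 of the differences.

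Before the data were examined, 25 gene lists were fixed. They hold genes of heme trafficking, other heme proteins, respiratory chain, iron, metal response, glutathione S-transferases, cytochrome P450s, UDP-glucuronosyltransferases, ABC transporters, oxidative stress defence, heat-shock proteins, cuticle collagens, molting, hypodermal antimicrobial peptides, innate immunity, sperm, oocyte and eggshell, germ line, vitellogenins, intestine, muscle, neurons, lipid metabolism, ribosomal proteins, and proteasome subunits. Each gene entered by its probe set of highest mean. Lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 25 lists, and again with an estimated correlation. With the estimated correlation only the heme trafficking list in the heme comparisons kept its call in the model above.

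The genes named were chosen by a rule fixed at the same time. For each comparison it takes hrg-2 and every measured heme trafficking gene. It adds, among genes past the threshold with non-overlapping groups, up to 10 largest rises and 10 largest falls in the comparisons of genotypes at each heme level and 5 of each elsewhere. Where fewer than 5 passed in a direction, the next genes with non-overlapping groups by smallest unadjusted p fill up to 5, named as not passing. For the difference between genotype effects, wildtype at 4 µM and mutant at 20 µM together must not overlap the other groups together. It also takes up to 4 members of smallest p from each list called. Genes with several probe sets are shown by that of highest mean, and others with the opposite sign are stated, as are that of R193.2 and, in the genotype comparisons, that of mrp-5. Outside the rule, gsto-1, ctsa-4.1, F43H9.4, ugt-17, cpr-8, F47D12.7, F47D12.9, dod-24 in the mutant and probe set 185275_at were chosen after their values were seen.

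The titles number the arrays 1 to 3 in each group. Deviations from the group means were compared between same-numbered arrays of the groups compared, and all 12 such pairs correlated across probe sets, with r from 0.255 to 0.817. The 6 same-numbered pairs of the remaining groups correlated at r from 0.101 to 0.702. Arrays of different numbers were not compared, and a shift of the arrays numbered 3 alone could give such values. They therefore do not show that numbers 1 and 2 pair the arrays, and the labels do not state it. The model above does not use the numbers, while the replicate block assumes that they pair the arrays. A fit with the replicate block, with 6 residual degrees of freedom, is given where it changes the call of a named gene or of a list, or moves a count given here by more than 1.5 times.

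Alternatives fixed in advance were centring each array on its median, repeated quantile normalization, a filter at the median of the mean values, a trended robust prior, no moderation, array weights, the replicate block, an added fold of at least 1.5, only the 2 groups compared, the fry test, the mean of a gene's probe sets, and leaving out each array. A fit on the arrays numbered 1 and 2 alone was added after seeing the data. Centring moved the median difference of all probe sets from 0.03 to 0.16 for the genotypes at 4 µM, from -0.02 to -0.16 for the difference between genotype effects and from -0.05 to -0.15 for heme in the mutant. List medians are given as deposited, and camera compares each list with the remaining genes. The procedure was tested on simulated data with 22548 probe sets for the genotype effect at 4 µM. It recovered 20.9% of 67 changes of log2 1, 67.2% of 67 changes of log2 2 and 87.9% of 66 changes of log2 4, with 0 false calls there and 1 for the difference between genotype effects. These false calls were counted on noise drawn separately for each probe set and array, without differences between replicate numbers. They therefore do not give the rate of false calls on the real arrays. With the replicate block the recovered shares were 11.9%, 61.2% and 86.4%, and with changes added to the real residuals they were 11.9%, 68.7% and 84.8%.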

Results

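The series compared hrg-2 mutant with wildtype C. elegans at low (4 µM) and higher (20 µM) heme, with 3 arrays in each of the 4 groups. HRG-2 is a membrane protein of the hypodermis, the worm's skin, with a role in heme utilization, and the comparisons address how its loss alters expression when heme is scarce or ample. The annotation used here pairs 0 probe sets with hrg-2, so its level could not be given and the genotype labels were not checked against it. Whether a probe set without a gene, such as 185275_at below, measures hrg-2 could not be told.

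In every group the array numbered 3 stood apart from those numbered 1 and 2. Sperm genes lay higher on it by a median of 2.69 log2 units over 72 measured genes, oocyte and eggshell genes by 1.51 over 24, and vitellogenins, the yolk proteins made by the adult intestine, by 1.65 over 5. The vitellogenin shift was -1.23 in wildtype at 4 µM, 4.78 in the mutant at 4 µM, 0.80 in wildtype at 20 µM and 3.43 in the mutant at 20 µM. The arrays numbered 3 correlated with each other at r from 0.962 to 0.982 and with the remaining arrays at r from 0.858 to 0.965, across probe sets, which are not independent replicates. In a comparison within groups chosen after the data were seen, 6789 probe sets differed between number 3 and numbers 1 and 2 by limma, 2581 higher and 4208 lower on number 3. This spread lies inside every group and enters the error of every comparison fitted without the replicate block. The block takes up the part that same-numbered arrays share, to a degree that differs by gene. For heme in wildtype it changed the SE from 0.50 to 0.16 for hrg-1 and from 0.37 to 0.36 for math-14.

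**Figure D1:**
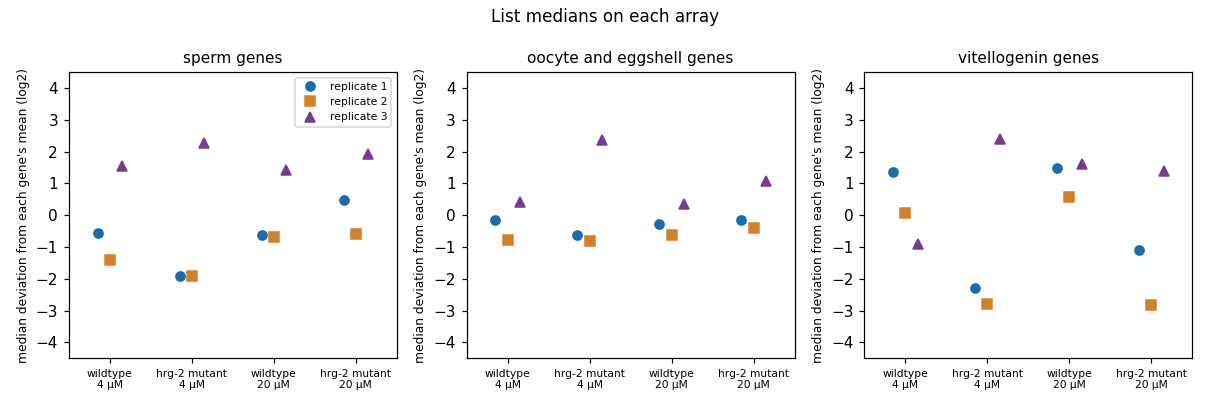
Median deviation of the sperm, oocyte and vitellogenin genes from each gene's mean over the 12 arrays (log2, vertical axis), 1 point per array, with the 4 groups along the horizontal axis and a marker for each replicate number. Sperm genes stood at 2.28 on mutant 4 µM replicate 3 and at -1.93 on replicate 1 of that group, while vitellogenins stood at -0.91 on wildtype 4 µM replicate 3 and at 2.39 on mutant 4 µM replicate 3.

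At 4 µM heme, the gene F47D12.6 (probe set 187668_at) was 73.4-fold lower in the mutant. Its log2 value was 8.93 ± 0.51 in wildtype and 2.74 ± 0.18 in the mutant (SD, n = 3), a difference of -6.20 ± 0.27 (SE) with an adjusted p of 9.44e-06 by limma. The mutant values lay near the lowest values on these arrays, which were 1.76 to 1.92, so the floor of the signal limits the fold. Probe set 185275_at, which has no gene in the annotation used, was 56.2-fold lower in the mutant, at 3.58 ± 0.41 against 9.39 ± 0.65 (difference -5.81 ± 0.50, adjusted p 0.00361, and 0.0607 with the 2 groups alone). For both probe sets every mutant array lay below every wildtype array. Of the 7 measured heme trafficking genes 0 passed by limma, over all genes or adjusted over the list alone, and 0 had an unadjusted p under 0.05. Their log2 differences were 0.12 for hrg-7, -0.08 for mrp-5 (another probe set -0.63), -0.22 for hrg-1, 0.36 for hrg-10, 0.21 for hrg-9 (another probe set -0.10), -0.09 for hrg-4 and -0.26 for hrg-3, with SEs of 0.24 to 0.55, and the list had a median of -0.08 and a mean of 0.01 (camera adjusted p 0.915). On the arrays numbered 1 and 2 alone hrg-9 passed by limma (0.87, adjusted p 0.039), as did 2922 of 22548 probe sets, while its pair numbered 3 differed by -1.13.

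As groups at 4 µM, the 48 measured respiratory chain genes (median log2 difference -0.14), the 45 glutathione S-transferases (-0.32), which act in detoxification, and the 33 proteasome subunits (-0.23) lay lower in the mutant relative to the remaining genes by camera, with adjusted p of 0.00254, 0.0025 and 4.86e-05. Each call was lost, at an adjusted p = 0.909 with an estimated correlation. These lists shifted by -0.19, -0.60 and -0.09 on the arrays numbered 3 over all groups. At 4 µM they shifted by -0.30, -0.74 and -0.48 in wildtype and by -0.34, -0.64 and -0.105 in the mutant. After median centring the medians were 0, -0.19 and -0.10. No member passed over all genes. Adjusted over the list alone, 1 glutathione S-transferase was lower, as was 1 of the 10 iron genes, and with the replicate block 2 iron genes, 1 collagen and 2 immune genes were lower. The glutathione S-transferases of smallest p were gst-27 (-1.18 ± 0.25), gst-38 (-0.57), gst-26 (-0.91) and gst-33 (-0.85). In the respiratory chain they were the ATP synthase subunits atp-3 (-1.32 ± 0.44) and atp-4 (-0.60) and the complex I subunits nduf-5 (-0.61) and nuo-5 (-0.73), and in the proteasome pas-5 (-0.91 ± 0.24), pbs-5 (-0.86), pbs-7 (-0.91) and rpn-12, whose difference was positive (0.53).

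In total 2 of 22548 probe sets passed at 4 µM by limma, both lower in the mutant, and 1378 had an unadjusted p under 0.05 (2573 with the block). By chance 1127 would be expected in each comparison. Without the block, genotype at 20 µM, the difference between genotype effects and heme in wildtype lay under that (379, 372 and 314). Such counts are therefore no estimate of how many probe sets changed. Among genes that did not pass and whose groups did not overlap, the smallest p values with a positive difference belonged to lips-16 (1.68 ± 0.23, adjusted p 0.151), F52E1.5 (1.21), fbxc-42 (0.78), scl-20 (1.09) and F47D12.3 (1.10). With a negative difference they belonged to C06B8.7 (-1.15), lec-12 (-0.80), pqn-89 (-1.27) and W07E11.1 (-1.05), with adjusted p from 0.563 to 0.791, and other probe sets of lec-12 and W07E11.1 gave 0.24 and 0.32. Without moderation 4 probe sets passed, lec-12 among them (adjusted p 0.0236), with the 2 groups alone 1, and above the median mean 0. Without wildtype 4 µM replicate 1 lips-16 passed (adjusted p 0.0134), and without mutant 4 µM replicate 3 the count was 5. The list count of 3 became 6 and 7 without wildtype replicates 2 and 3, and 9, 10 and 10 without mutant replicates 1, 2 and 3, while median centring gave 7. With the replicate block 5 lists were called, the cuticle collagens, lower (median -0.20, adjusted p 0.00784), and the oocyte genes, higher (0.43, 0.00657), being added. Both were lost, at an adjusted p = 0.845 with an estimated correlation, and on the arrays numbered 1 and 2 alone the oocyte genes were lower (-0.29, 0.0261). The respiratory chain call ended without wildtype replicate 1 (adjusted p 0.138) and that of glutathione S-transferases without wildtype replicate 2 or mutant replicate 3 (up to 0.167). When only the arrays numbered 1 and 2 were used, a choice made after seeing the data, 2922 probe sets passed, 1168 higher and 1754 lower, and 33.7% of them had the same sign on the pair numbered 3.

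At 20 µM heme F47D12.6 was again lower in the mutant, 74.4-fold, with 8.94 ± 0.31 in wildtype and 2.72 ± 0.25 in the mutant (SD, 3 arrays each). The difference of -6.22 ± 0.27 had an adjusted p of 9.13e-06 by limma and was the only one among 22548 probe sets to pass (1 call, lower), with 379 at an unadjusted p under 0.05 (1463 with the replicate block). Probe set 185275_at stood at 4.39 ± 1.04 in wildtype and 3.59 ± 0.37 in the mutant (-0.80 ± 0.50, adjusted p 1). Of the 7 heme trafficking genes 0 passed by limma, also adjusted over the list alone, and 0 had an unadjusted p under 0.05. Their log2 differences were 0.13 for hrg-7, -0.15 for mrp-5 (another probe set -0.24), 0.25 for hrg-1, 0.50 for hrg-10, -0.40 for hrg-9, -0.68 for hrg-4 and 0.07 for hrg-3. With the block 1 had an unadjusted p under 0.05, hrg-4 (SE 0.20, p 0.00737, adjusted p 0.649 by limma), which was lower in the mutant in all 3 pairs (-0.78, -0.27 and -0.98).

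Among the gene groups at 20 µM, camera placed glutathione S-transferases (median -0.29, adjusted p 0.000944), heat-shock proteins (-0.19, 0.00128), vitellogenins (-2.36, 0.012) and intestinal markers (-0.25, 0.00253) lower in the mutant. Hypodermal antimicrobial peptides (0.23, 0.00218), sperm genes (0.62, 0.000944) and ribosomal proteins (0.10, 4.57e-05) were placed higher. All 7 calls were lost, at an adjusted p = 0.992 with an estimated correlation, and no member passed, also adjusted over the list alone. The shifts on the arrays numbered 3 over all groups were -0.60 for glutathione S-transferases, -0.03 for heat-shock proteins, 1.65 for vitellogenins, -0.30 for intestinal markers, -0.09 for antimicrobial peptides, 2.69 for sperm genes and 0.04 for ribosomal proteins. In wildtype and mutant at 20 µM the shifts were unequal for several lists. They were -0.77 and -0.03 for glutathione S-transferases, -0.49 and 0.045 for heat-shock proteins and -0.36 and 0.002 for intestinal markers. Members of smallest p among the chaperones were the small heat-shock genes hsp-16.41 (-1.97 ± 0.57) and hsp-16.2 (-2.50 ± 0.91), hsp-70 (-1.90) and hsp-2 (-0.31). The yolk protein genes were vit-4 (-2.59 ± 1.48, another probe set 0.10), vit-5 (-2.36), vit-2 (-2.41) and vit-6 (-2.02), and the intestinal genes the GATA factor elt-2 (-1.17 ± 0.37), ifc-2 (-0.42), cpr-4 (-0.22) and ifd-2 (-0.38). The glutathione S-transferases were gst-12 (-1.12), gst-44 (1.01), gst-16 (-0.66) and gst-27 (-0.49), and the antimicrobial peptides cnc-2 (0.77), nlp-33 (-0.26), nlp-29 (0.32) and cnc-8 (0.27). The sperm genes were spe-4 (0.64), spe-48 (-0.25), spe-44 (0.74) and spe-51 (0.36), and the ribosomal genes rps-21 (0.26), rpl-9 (0.27), rpl-35 (0.27) and rps-23 (0.26).

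Genes of smallest p among those with non-overlapping groups that did not pass at 20 µM were F47D12.3 (1.37 ± 0.24), cdk-5 (0.80), spp-12 (2.20), gtnt-8 (1.11) and Y38E10A.9 (1.83), then F44A2.7 (-1.02), F43H9.4 (-1.5), F45E1.4 (-0.88) and gadr-3 (-1.01), each with an adjusted p of 1. With the replicate block 9 lists were called, with metal response genes, lower (median -0.24, adjusted p 0.0422), and oocyte genes, higher (0.29, 0.0111), added. These were lost, at an adjusted p = 0.723 and 0.991 with an estimated correlation. Without mutant replicate 3 the sperm median was -0.08 and the sperm call ended, as it did without wildtype replicates 1 or 2 (adjusted p up to 0.815). The vitellogenin call ended without wildtype replicate 3 or mutant replicates 1 or 2 (up to 0.43), those of glutathione S-transferases (0.478) and intestinal markers (0.0594) without wildtype replicate 2, and that of ribosomal proteins without mutant replicate 3 (0.546). With array weights 67 probe sets passed, 35 higher and 32 lower, and above the median mean 0. On the arrays numbered 1 and 2 alone 275 probe sets passed, 129 higher and 146 lower, and 38.2% of them had the same sign on the pair numbered 3.

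**Figure D2:**
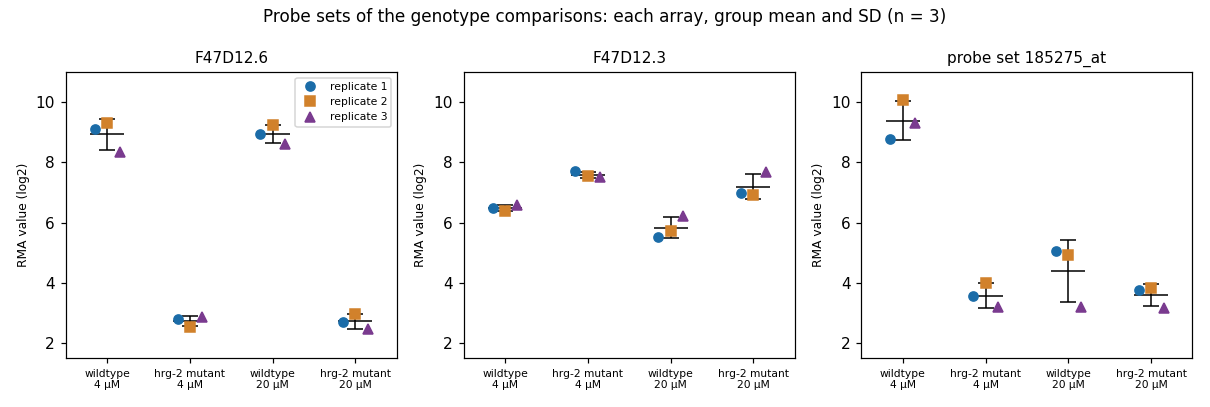
Deposited log2 values (vertical axis) of F47D12.6, F47D12.3 and probe set 185275_at on each array (points, marked by replicate number) in the 4 groups, with group means (dashes) and SDs (bars, n = 3). The group means of F47D12.6 were 8.93 and 8.94 in wildtype and 2.74 and 2.72 in the mutant, and probe set 185275_at stood at 9.39 in wildtype at 4 µM and between 3.58 and 4.39 in the remaining groups.

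Averaged over both heme levels, F47D12.6 differed by -6.21 ± 0.19 (adjusted p 2.8e-07) and probe set 185275_at by -3.31 ± 0.35 (adjusted p 0.0281) by limma, and these were the 2 of 22548 probe sets to pass, both lower in the mutant (1393 at an unadjusted p under 0.05, and 3091 with the replicate block). With array weights 871 passed, 309 higher and 562 lower, and above the median mean 0. The call of 185275_at ended without moderation (0.144) and in 10 of 12 fits with 1 array left out (adjusted p 0.0715 to 0.165), all but those without wildtype 4 µM replicate 1 or wildtype 20 µM replicate 3. The count was 1 in those 10 fits and 3 without wildtype 4 µM replicate 1. Of the heme trafficking genes 0 passed, also adjusted over the list alone, and 1 had an unadjusted p under 0.05, hrg-10 (0.43 ± 0.18), joined with the block by hrg-4 (p 0.0222, adjusted p 0.28 by limma). The remaining differences were 0.13 for hrg-7, -0.11 for mrp-5 (another probe set -0.44), 0.02 for hrg-1, -0.10 for hrg-9, -0.39 for hrg-4 and -0.09 for hrg-3. On the arrays numbered 1 and 2 alone hrg-10 passed by limma (0.55, adjusted p 0.0383), as did 2996 of 22548 probe sets. Genes of smallest p among those with non-overlapping groups that did not pass were F47D12.3 (1.23 ± 0.17, adjusted p 0.132), srv-15 (0.60), E01G4.5 (0.90), pho-14 (0.68) and try-13 (0.87), and W02D7.8 (-0.98), gadr-3 (-0.91), cat-6 (-0.85) and F44A2.7 (-0.80), with adjusted p from 0.503 to 0.737 after the first.

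Camera called 10 lists in the averaged comparison. Lower in the mutant were glutathione S-transferases (median -0.32, adjusted p 8.69e-05), 32 oxidative stress defence genes (-0.11, 0.0303), 21 heat-shock proteins (-0.26, 0.00268), 145 cuticle collagens (-0.19, 0.0305), vitellogenins (-1.80, 0.033), 21 intestinal markers (-0.23, 0.0161) and proteasome subunits (-0.08, 0.0305). Higher were 18 hypodermal antimicrobial peptides (0.17, 0.0305), oocyte genes (0.37, 0.0305) and 75 ribosomal proteins (0.08, 0.00429). No call held, at an adjusted p = 0.951 for collagens and oocyte genes and 0.947 for the others with an estimated correlation. After median centring the medians were -0.05 for oxidative stress genes, -0.12 for collagens, 0.15 for ribosomal proteins and -0.01 for the proteasome. Collagens shifted by 0.44 on the arrays numbered 3, oxidative stress genes by -0.31 and the remaining lists as given above. Adjusted over the list alone, 2 heat-shock genes, 1 glutathione S-transferase and 1 iron gene were lower. With the block 4 heat-shock genes, 5 glutathione S-transferases, 1 UDP-glucuronosyltransferase and 2 immune genes were lower, and 1 glutathione S-transferase and 1 sperm gene higher. The heat-shock genes of smallest p were hsp-16.41 (-1.77 ± 0.40), hsp-16.2 (-2.62 ± 0.64), hsp-3 (-0.75) and hsp-70 (-1.73), and the antioxidant genes the superoxide dismutases sod-2 (-0.72) and sod-1 (-0.49), gpx-6 (-0.63) and trxr-1 (-0.40).

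Further members of smallest p in the averaged comparison were gst-27 (-0.83), gst-44 (0.81), gst-26 (-0.67) and gst-13 (-1.04), the collagens col-182 (-0.83), col-153 (0.51), col-73 (-0.46) and col-111 (-0.76), and the yolk genes vit-4 (-2.07, another probe set 0.18), vit-5 (-1.80), vit-2 (-2.03) and vit-6 (-1.63). Others were elt-2 (-0.88 ± 0.26), cpr-6 (-0.50), cpr-5 (-0.30) and ges-1 (-0.30) of the intestine, pie-1 (0.80), puf-7 (0.72), egg-2 (0.86) and chs-1 (0.59) of the oocyte, and cnc-8 (0.32), nlp-24 (0.30), cnc-5 (0.23) and cnc-4 (0.58). Ribosomal and proteasome genes were rpl-39 (0.28), rpl-35 (0.23), rps-11 (0.21) and rpl-34 (0.26), and pas-5 (-0.45), pas-1 (-0.50), pbs-5 (-0.39) and rpt-2 (0.31). The proteasome call ended after median centring (adjusted p 0.0787), with repeated quantile normalization (0.0998) and with the replicate block (0.0866), and the oocyte call with centring (0.0866). The calls of oxidative stress genes, collagens and vitellogenins ended with repeated quantile normalization (0.0552, 0.0887 and 0.0522). Sperm genes were added with the block (median 0.23, adjusted p 0.0117), a call lost at an adjusted p = 0.851 with an estimated correlation. On the arrays numbered 1 and 2 alone the medians of sperm and oocyte genes were negative (-0.12 and -0.07), at camera adjusted p of 0.404 and 0.314. The vitellogenin median there was -3.46, with 4 of 5 genes lower over all genes. Of the glutathione S-transferases 17 were lower and 2 higher there, and 8 heat-shock genes were lower. With an estimated correlation none of these lists was called there (camera adjusted p 0.41 for vitellogenins, glutathione S-transferases and heat-shock proteins). The oocyte list stood at 2.37 on mutant 4 µM replicate 3, against -0.63 and -0.83 on replicates 1 and 2 of that group, and without that array its median was -0.11. The list count was 6 without wildtype 4 µM replicate 2 or mutant 20 µM replicate 1, and 2996 probe sets passed when only the arrays numbered 1 and 2 were used, 1187 higher and 1809 lower.

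With 1 array left out, the averaged calls of glutathione S-transferases and heat-shock proteins stood in all 12 fits. The call of ribosomal proteins ended without mutant 20 µM replicate 3 (adjusted p 0.278), that of intestinal markers without wildtype 4 µM replicate 2 or mutant 4 µM replicate 3 (up to 0.142), and that of oocyte genes without replicate 2 of wildtype or replicate 3 of the mutant at either heme level (up to 0.431). Collagens ended without replicate 3 of wildtype at either level, mutant 4 µM replicate 1 and mutant 20 µM replicates 1 and 2 (up to 0.967). Without mutant 20 µM replicate 1 camera placed them higher, at a median of -0.07. Oxidative stress genes ended without replicates 1 or 2 of wildtype at either level and mutant 4 µM replicate 3 (up to 0.142). Vitellogenins ended without replicates 1 or 3 of wildtype or 1 or 2 of the mutant at either level (up to 0.194). Antimicrobial peptides ended without wildtype 4 µM replicate 2, wildtype 20 µM replicate 3 and replicates 1 or 2 of the mutant at either level (up to 0.125). Proteasome subunits ended without wildtype 4 µM replicates 1 and 2, wildtype 20 µM replicates 1 and 3, mutant 4 µM replicate 1 and mutant 20 µM replicates 1 and 2 (up to 0.499).

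The genotype effects at 4 and 20 µM, which share no array, correlated across the 22548 probe sets at r = 0.415 (Spearman 0.379), with the same sign in 62%, though genes are not independent replicates. Without mutant 4 µM replicate 3 the correlation was -0.000459 and without wildtype 4 µM replicate 2 it was 0.0525. It was 0.344 with the arrays numbered 1 and 2 alone. The deviations of same-numbered arrays from their group means also correlated between the heme levels, at up to 0.817 in wildtype and 0.636 in the mutant. Differences between replicate numbers can therefore enter both genotype effects, which are not independent estimates.

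The test of whether the genotype effect differed between 4 and 20 µM called 0 of 22548 probe sets by limma, with 372 at an unadjusted p under 0.05 (727 with the replicate block), and array weights called 1, probe set 185275_at. The estimate for probe set 185275_at was 5.01 ± 0.71 (adjusted p 0.674, and 0.053 with the replicate block). Of the heme trafficking genes 0 passed, also adjusted over the list alone, and 0 had an unadjusted p under 0.05. The estimates were 0.00 for hrg-7, -0.06 for mrp-5 (another probe set 0.39), 0.46 for hrg-1, 0.14 for hrg-10, -0.61 for hrg-9, -0.58 for hrg-4 and 0.33 for hrg-3. Among genes for which all arrays of wildtype at 4 µM and mutant at 20 µM lay on 1 side of all those of the other groups, the smallest p belonged to timm-23 (0.87), let-502 (0.88), tin-10 (0.61), fbxb-48 (0.46), Y41D4B.24 (0.52), sre-24 (-0.63), Y55B1AR.2 (-1.09), apt-9 (-0.76), hlh-14 (-0.75) and lgc-48 (-0.58), each at an adjusted p of 1, and other probe sets of let-502 and Y41D4B.24 gave -0.17 and -0.11. Camera called respiratory chain (median 0.17, adjusted p 0.00124), sperm (0.90, 0.00221), germ line (0.17, 0.0332) and proteasome (0.33, 3.53e-07) genes as more positive at 20 µM, and each call was lost, at an adjusted p = 0.957 with an estimated correlation. After median centring the medians were 0.03 for the respiratory chain, 0.03 for the germ line and 0.20 for the proteasome, and with repeated quantile normalization that of the respiratory chain was 0.11. Members of smallest p were nduf-5 (0.65), cox-15 (0.62), nuo-5 (0.68) and atp-3 (0.99) of the respiratory chain, pas-5 (0.91), pbs-7 (1.10), pbs-5 (0.94) and rpn-12 (-0.65) of the proteasome, spe-36 (-0.82), spe-44 (1.25), spe-40 (0.30) and msp-53 (1.67) of sperm, and the germ line genes fbf-1 (0.96), glh-1 (0.47), fbf-2 (0.79) and htp-1 (0.69). The shift on the arrays numbered 3 was 0.45 for the germ line list, 2.69 for sperm, -0.19 for the respiratory chain and -0.09 for the proteasome. The germ line call ended with the replicate block (adjusted p 0.1) and with repeated quantile normalization (0.222), and the list count was 8 and 7 without replicate 3 of wildtype at 4 and 20 µM, and 2 without wildtype 20 µM replicate 1. The respiratory chain call ended without wildtype 4 µM replicate 1 (adjusted p 0.0961). The sperm and germ line calls ended without wildtype 4 µM replicate 3, wildtype 20 µM replicates 1 and 2, mutant 4 µM replicates 1 and 2 and mutant 20 µM replicate 3 (up to 0.982 and 0.892). The germ line call ended also without mutant 20 µM replicate 2. Without mutant 4 µM replicate 1 the germ line median was -0.01.

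In wildtype animals, expression of heme trafficking genes fell from 4 to 20 µM heme. It fell 41.2-fold for hrg-3, an exported heme-binding protein (8.01 ± 0.47 to 2.65 ± 0.30 on the log2 scale, SD, n = 3, difference -5.36 ± 0.31, adjusted p 7.94e-05 by limma). It fell 18.3-fold for hrg-7, a protein related to aspartic proteases (-4.19 ± 0.24, 7.94e-05), and 19-fold for the heme importer hrg-4 (-4.25 ± 0.55, 0.0379). Of the 7 measured members, 3 passed over all genes and 6 adjusted over the list alone, all lower at 20 µM. The heme transporter hrg-1 differed by -3.42 ± 0.50 (adjusted p 0.101), the heme exporter mrp-5 by -1.48 ± 0.31, hrg-9 by -0.78 and hrg-10 by -0.62 (adjusted p 1 each). The list median was -3.42 (camera adjusted p 9.64e-40, and adjusted p = 0.00275 with an estimated correlation). The list was defined as heme-responsive genes and heme transport, so its call in either heme comparison checks the data and is no new result. On the arrays numbered 3 the list shifted by -0.50 over all groups, and by -0.10 and -0.48 in wildtype at 4 and 20 µM. Outside the list, math-14 fell by 4.48 ± 0.37 (22.4-fold, adjusted p 0.00144), R193.2 fell by 3.82 ± 0.47 (0.0325, another probe set -1.13), the glutathione transferase gsto-1 fell by 2.82 ± 0.34 (0.0325) and ctsa-4.1 fell by 2.04 ± 0.26 (0.0343). Probe set 185275_at fell by 5.00 ± 0.50 (adjusted p 0.00756). In wildtype at 20 µM hrg-3 (2.38 to 2.98) and math-14 (2.92 to 3.15) lay near the lowest values on these arrays, 1.76 to 1.92. The floor of the signal therefore limits their folds.

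**Figure D3:**
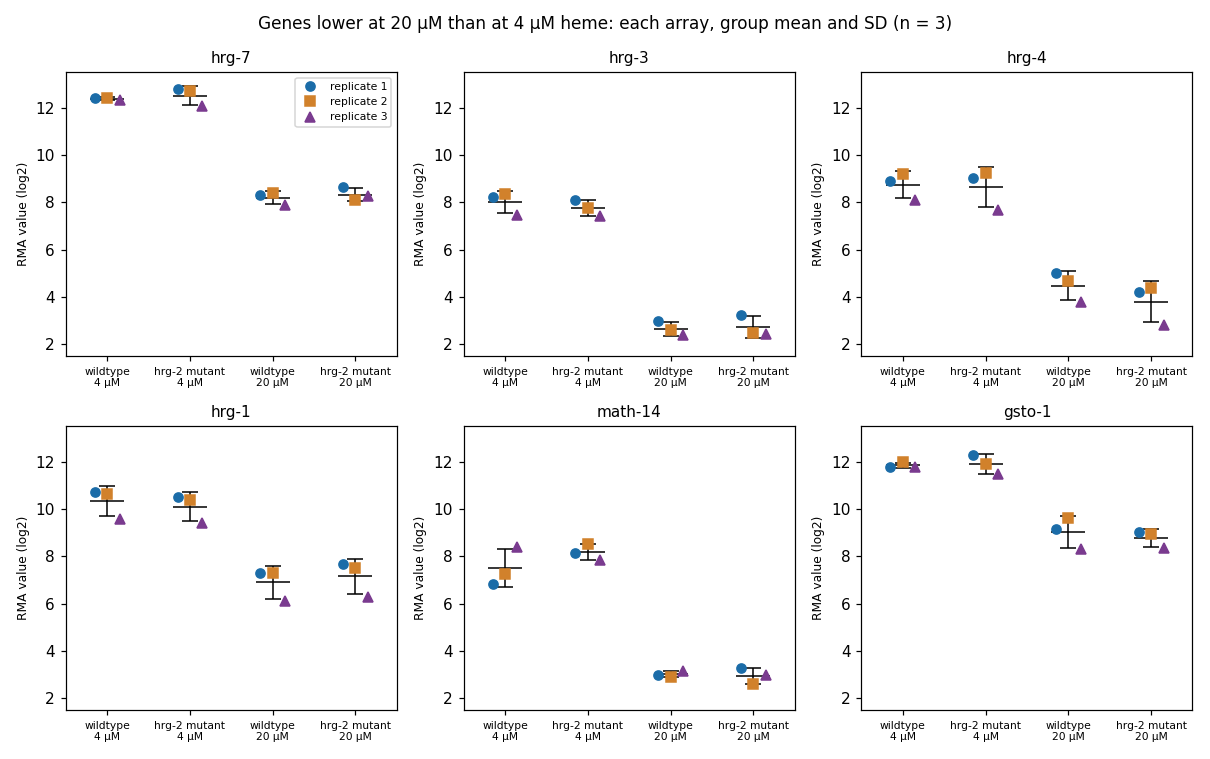
Deposited log2 values (vertical axis) of hrg-7, hrg-3, hrg-4, hrg-1, math-14 and gsto-1 on each array (points, marked by replicate number) in the 4 groups, with group means (dashes) and SDs (bars, n = 3). In both genotypes every 20 µM array lies below every 4 µM array for these genes, and the mean of hrg-3 goes from 8.01 to 2.65 in wildtype and from 7.75 to 2.72 in the mutant.

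In total 8 of 22548 probe sets passed in wildtype, all lower at 20 µM, and 314 had an unadjusted p under 0.05 (689 with the replicate block). With array weights 15 passed, all lower, above the median mean 5, without moderation 3 and with the 2 groups alone 2. With the replicate block 15 passed, 1 higher and 14 lower, among them 4 heme trafficking genes with hrg-1 (adjusted p 1.17e-05), then cpr-8 (-2.55, adjusted p 0.154 without the block and 0.00931 with it), a further probe set of mrp-5 (-1.82, 0.0193) and, as the one that was higher, dod-24 (1.92, adjusted p 1 without the block and 0.0163 with it). The calls of hrg-3, hrg-7 and math-14 stood in all 6 fits that left out 1 array, and that of math-14 ended with the 2 groups alone (adjusted p 0.271). Also ended with the 2 groups alone were the calls of hrg-4 (0.34), R193.2 (0.418), gsto-1 (0.47), ctsa-4.1 (0.478) and 185275_at (0.458). Without moderation the calls ended of hrg-4 (0.304), R193.2 (0.228), gsto-1 and ctsa-4.1 (0.183 each) and 185275_at (0.0951). That of hrg-4 ended with repeated quantile normalization too (0.0557). With 1 array left out those of hrg-4 and ctsa-4.1 ended in all 6 (adjusted p 0.0865 to 0.293 and 0.0865 to 0.254), R193.2 in all but the fit without 4 µM replicate 3 (0.108 to 0.254), gsto-1 in all but the fit without 20 µM replicate 2 (0.0653 to 0.254), and 185275_at without 4 µM replicate 2 (0.0521). Without replicates 1, 2 and 3 of the 4 µM arrays 4, 3 and 5 probe sets passed, and without those of the 20 µM arrays 4, 5 and 4. With numbers 1 and 2 alone 55 passed, 27 higher and 28 lower.

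Of other groups in wildtype, heat-shock proteins were higher at 20 µM (median 0.22, camera adjusted p 7.59e-05), a call lost at an adjusted p = 0.264 with an estimated correlation. Members of smallest p were hsp-16.41 (1.8 ± 0.57), hsp-4 (0.54), hsp-70 (2.33) and hsp-16.2 (2.08), none of which passed. The 280 immune genes were also higher (0.05, 0.0151), and 51 neuronal markers (-0.11, 0.0189) and ribosomal proteins (-0.07, 0.0185) lower, each lost at an adjusted p = 0.934 with an estimated correlation. The shifts on the arrays numbered 3 over all groups were -0.03 for heat-shock proteins, -0.40 for neuronal markers and 0.04 for ribosomal proteins, and near 0 for immune genes. In wildtype at 4 and 20 µM they were -0.07 and -0.49 for heat-shock proteins and -0.54 and -0.47 for neuronal markers. Members of smallest p were clec-140 (0.85), clec-101 (0.63), spp-6 (-1.16) and dod-24 of the immune genes, unc-18 (-0.51), flp-21 (-0.58), cat-2 (-0.39) and flp-6 (-0.36) of the neurons, and rps-21 (-0.25), rps-23 (-0.29), rps-10 (-0.24) and rps-29 (-0.25). After median centring the medians were 0.08 for immune genes, -0.07 for neuronal markers and -0.03 for ribosomal proteins. The ribosomal call ended after centring (adjusted p 0.177) and repeated quantile normalization (0.0823). Adjusted over the list alone, 2 glutathione S-transferases, 1 UDP-glucuronosyltransferase and 1 ABC transporter were lower. With the block 5 UDP-glucuronosyltransferases were lower and 1 immune gene higher. With the block UDP-glucuronosyltransferases were also called as a list, lower (median -0.12, adjusted p 0.00118), and sperm genes higher (0.12, 0.0289), lost at an adjusted p = 0.735 and 0.846 with an estimated correlation. Without 20 µM replicate 3 the neuronal median was 0.02 and that call ended, as it did without 4 µM replicates 1 or 2 (adjusted p up to 0.935). The immune call ended without replicate 2 at either level (up to 0.149), and the ribosomal call without 4 µM replicate 3 or 20 µM replicate 2 (up to 0.453). The list count of 5 became 8 and 13 without 4 µM replicates 1 and 3, and 9 and 8 without 20 µM replicates 2 and 3. Among genes with non-overlapping groups the smallest p with a positive difference, none passing, belonged to F45E1.4 (0.87), kpc-1 (1.08), clec-140, tps-2 (1.18) and M60.7 (1.35), each at an adjusted p of 1.

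In the mutant, hrg-3 fell by 5.03 ± 0.31 from 4 to 20 µM (32.7-fold, adjusted p 0.000149 by limma), hrg-7 fell by 4.19 ± 0.24 (18.2-fold, 0.000126) and hrg-4 fell by 4.83 ± 0.55 (28.5-fold, 0.0159). As in wildtype, 3 heme trafficking genes passed over all genes and 6 of 7 adjusted over the list alone, all lower, with hrg-1 at -2.95 ± 0.50 (adjusted p 0.203), mrp-5 at -1.54 (0.382), hrg-9 at -1.39 (0.769) and hrg-10 at -0.49 (0.821). The list median was -2.95 (camera adjusted p 1.26e-19, and adjusted p = 0.0294 with an estimated correlation). Also lower and past the threshold were math-14 (-5.23 ± 0.37, 37.5-fold, 0.000323), R193.2 (-3.67, 0.0347, another probe set -0.84), gsto-1 (-3.12, 0.0159), ctsa-4.1 (-2.14, 0.0221), F43H9.4 (-2.96, 0.0159) and the glucuronosyltransferase ugt-17 (-2.37, 0.0387). In wildtype F43H9.4 differed by -1.77 (adjusted p 0.509) and ugt-17 by -1.84 (0.249), and the test of the difference between genotypes, which called 0 probe sets by limma, called neither. The heme difference of probe set 185275_at in the mutant was 0.01 ± 0.50, and its contrast with the fall in wildtype had an adjusted p of 0.674. In the mutant at 20 µM hrg-3 (2.45 to 3.25), math-14 (2.61 to 3.29) and hrg-4 on replicate 3 (2.80) lay near the floor, which limits their folds.

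In total 9 probe sets passed in the mutant, all lower at 20 µM, with 1389 at an unadjusted p under 0.05 (2825 with the replicate block), and 7 were shared with the 8 of wildtype, where independent lists would share 0.00319. With the replicate block 18 passed, 3 higher and 15 lower, with 4 heme trafficking genes including hrg-1 (adjusted p 3.03e-05), cpr-8 (-2.27, adjusted p 0.23 without the block and 0.0213 with it) and dod-24 (2.58, 0.769 and 0.00165) among them, and 12 of these 18 were shared with wildtype. With array weights 1004 passed, 367 higher and 637 lower, without moderation 4 and with the 2 groups alone 3. Without mutant 4 µM replicate 3 the count was 49, cpr-8 then passing (adjusted p 0.00895), without mutant 20 µM replicate 3 it was 4 and without each of the remaining 4 arrays it was 3. The calls of hrg-3, hrg-7 and math-14 stood in all 6 fits. With 1 array left out those of hrg-4, R193.2, gsto-1, ctsa-4.1 and ugt-17 stood only without mutant 4 µM replicate 3, with adjusted p up to 0.15, 0.294, 0.132, 0.186 and 0.311 otherwise, and that of F43H9.4 also without mutant 20 µM replicate 3 (0.107 to 0.15 otherwise). These 6 calls also ended with the 2 groups alone (adjusted p 0.245 for gsto-1 and 0.293 for the others). Without moderation they ended as well (0.122 for hrg-4, 0.141 for R193.2, 0.135 for ugt-17 and 0.0928 for the others). With numbers 1 and 2 alone 3167 probe sets passed, 1682 higher and 1485 lower.

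Several gene groups were higher at 20 µM in the mutant by camera. These were proteasome subunits (median 0.45, adjusted p 1.09e-12), respiratory chain (0.18, 9.71e-06), sperm (1.20, 1.49e-06), 25 germ line (0.26, 0.00479), heat-shock (0.15, 0.0135) and 86 lipid metabolism (0.17, 0.0143) genes. The calls were lost, at an adjusted p = 0.447 for the proteasome, 0.544 for respiratory chain, heat shock and lipid metabolism, and 0.989 for sperm and germ line, with an estimated correlation. After median centring the medians were 0.09 for the respiratory chain, 0.16 for the germ line, 0.05 for heat shock and 0.07 for lipid metabolism. Lipid genes shifted by -0.27 on the arrays numbered 3 over all groups, sperm genes by 2.69, germ line genes by 0.45 and the remaining lists as given above. In the mutant at 4 and 20 µM sperm genes shifted by 4.21 and 1.98 and germ line genes by 1.14 and 0.07. The respiratory chain shifted there by -0.34 and 0.06, and the proteasome by -0.105 and 0.18. Members of smallest p were pas-5 (0.75), pbs-5 (0.93), rpt-1 (0.55, another probe set -0.07) and pbs-7 (0.84) of the proteasome, and atp-3 (1.23), nduf-5 (0.63), atp-4 (0.50) and nuo-5 (0.64) of the respiratory chain. They were hsp-3 (1.15), hsp-4 (0.55), hsp-16.2 (2.31) and hsp-16.41 (1.39) among chaperones, fbf-2 (0.95), fbf-1 (0.83), glh-1 (0.31) and glh-4 (1.01) in the germ line, spe-40 (0.45), spe-36 (-0.84), spe-44 (1.33) and spe-4 (0.78) in sperm, and the fatty acid synthase fasn-1 (0.84), ech-1.2 (0.68), acs-22 (0.83) and ech-8 (-0.75) in lipid metabolism. None of them passed over all genes. Adjusted over the list alone, 2 glutathione S-transferases, 1 UDP-glucuronosyltransferase and 1 ABC transporter were lower, and among metal response genes 1 was higher and 1 lower. With the block 10 UDP-glucuronosyltransferases were lower, and 11 collagens, 2 iron genes, 1 oxidative stress gene and 1 immune gene higher. The collagen list median was however negative (-0.15). On the arrays numbered 1 and 2 alone it was -0.43, with 33 collagens lower and 9 higher over all genes. The calls of heat-shock and sperm genes ended without 4 µM replicates 1 or 2 or 20 µM replicate 3 (adjusted p up to 0.0955 and 0.274). That of germ line genes ended without 4 µM replicates 1 or 2 (up to 0.526), and that of lipid genes without 4 µM replicates 2 or 3 or 20 µM replicates 1 or 2 (up to 0.0594). The list count was 4 without mutant 4 µM replicate 2 and 11 with numbers 1 and 2 alone. Among genes with non-overlapping groups the smallest p with a positive difference, none passing, belonged to W07E11.1 (1.20), valv-1 (1.52), F10C2.7 (2.83), ptc-3 (1.29) and K12H6.6 (0.81), with adjusted p from 0.254 to 0.382.

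Of the 25 lists, 8 were called in no comparison by camera in the fit on all arrays without the replicate block. The lowest camera adjusted p was 0.249 for the 53 heme proteins outside trafficking, 0.147 for the 10 iron genes, 0.0855 for the 10 metal response genes, 0.395 for the 73 cytochrome P450s, 0.0543 for the 64 UDP-glucuronosyltransferases, 0.512 for the 51 ABC transporters, 0.109 for the 111 molting genes and 0.11 for the 27 muscle markers. In that fit their medians over the comparisons lay between -0.27 and 0.27. Lists added by the block are given above. On numbers 1 and 2 alone molting genes were called lower at 20 µM in wildtype (median -0.24, camera adjusted p 0.000143). They were also lower in the mutant (-0.39, 0.00427). With an estimated correlation the adjusted p there was 0.0425 in wildtype and 0.117 in the mutant, for molting and for heme trafficking genes. Iron, metal response, UDP-glucuronosyltransferase and muscle lists were also called there in some comparisons.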

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

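Tests chosen only after the result was seen were the comparison of the arrays numbered 3 with numbers 1 and 2, those of males, of the normalization, of a dim probe set, of the neighbouring genes and of loss of hrg-2 function, the requirement that single pairs bear out the stage correlation, the requirement that col-19 order the genotypes alike on all 3 pairs, the count of all splits that part every replicate number, and the fit on the arrays numbered 1 and 2 alone.

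The difference between the genotype effects at 4 and 20 µM passed camera's test for 4 gene lists, with medians of 0.17 for the respiratory chain, 0.90 for sperm, 0.17 for the germ line and 0.33 for the proteasome, and was lost for each with an estimated correlation (adjusted p = 0.957). Among 100 splits of the 12 arrays, 94 called as many lists (real 4, highest other 16), so chance was not excluded for these calls.

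The arrays numbered 3 stood apart from numbers 1 and 2 in all 4 groups. Repeated quantile normalization left 100.5% of the sperm list's shift. This does not decide on normalization, which stays open: the deposited values were already normalized, with array medians at most 0.114 from their mean, so repeating it could move little. Males mixed into these samples were argued against as the whole source, since the oocyte list was higher too, by 1.51. A later stage of the animals on these arrays is a candidate explanation that passed its test, in that col-19, a collagen gene of the adult stage, was higher on number 3 in all 4 groups, by 2.17 to 5.40 (log2). The vitellogenin shift of -1.23 in wildtype at 4 µM goes against a shared stage shift for that list, and none of the groups of the design separates the replicate numbers.

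F47D12.6 was lower on all 6 mutant arrays. A probe set that fails in the mutant strain alone stays open: the gap of 5.38 log2 units between the lowest wildtype and the highest mutant array is the pattern itself, and the mutant arrays (2.48 to 2.98) lie near the floor. A difference of the strain at or around this gene stays open: the 20 neighbouring measured genes had a median absolute genotype effect of 0.201 against 0.177 over all 17138 windows, at percentile 65.7. A change limited to 1 gene would leave its neighbours as they are, and a change of a few genes would hardly move a median of 20. In the gene order of WBcel235, gadr-3 (-0.91 ± 0.17) is the next measured gene on 1 side. On the other side F47D12.7 (-1.58 ± 0.77), F47D12.3 (1.23 ± 0.17) and F47D12.9 (-0.60 ± 0.28) follow in that order. None of these passed by limma, with adjusted p of 0.503 for gadr-3 and 0.132 for F47D12.3. On the arrays numbered 1 and 2 alone, where 2996 of 22548 probe sets passed, these were 0.00411 and 0.00216. Both were among the genes of smallest p named in the averaged comparison. An unadjusted p under 0.05 was found for 3 of the 20 neighbours, and for 1393 of all 22548 probe sets. F47D12.6 and hrg-2 lie on different chromosomes. Loss of hrg-2 function could give the fall as well, present at both heme levels (the smaller difference -6.20), and it cannot be told apart from a strain difference because each genotype is 1 strain in this design.

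Genotype differences at 4 µM were called for 2922 probe sets on the arrays numbered 1 and 2 alone. Of these, 33.7% had the same sign on the pair numbered 3 (29.5% of those higher and 36.5% of those lower), where 43% of all probe sets were higher. Genotype stays open as their source although this lies under the bound of 55% set beforehand, because that bound took the animals of the pair to be of like stage: col-19 was lower in the mutant on pairs 1 and 2 (7.61 against 8.61 and 7.15 against 7.95) and higher on pair 3 (12.78 against 10.86), and 1 pair excludes nothing. A difference in developmental stage between the genotypes stays open too: across probe sets these effects correlated with the number 3 difference of wildtype at 20 µM at r = 0.092, while single pairs gave -0.047 and 0.217 and the mutant axis -0.072. The counterpart at 20 µM, with the number 3 difference of wildtype at 4 µM and no bound set beforehand, gave r = 0.586. Yet col-19, which is higher on number 3, was lower in the mutant on pairs 1 and 2 at 20 µM (7 against 8.86 and 6.76 against 8.82). These gauges of stage therefore disagree at 20 µM.

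Chance was tested by splitting the same arrays in other ways. For the genotype effect averaged over heme, 2 of 100 splits called as many probe sets (real 2), and the other of these called 1250, which points to a structure of the samples. Most of the 100 put arrays of the same number together. Of all 32 splits that part every replicate number, only the real one called as many (highest other 0), a share of 0.0312, under 0.05 but also the smallest that 32 splits can give. With the replicate block 2 of the 32 did (real 2, highest other 291), a share of 0.0625, so chance was not excluded for the count in that fit. These splits compare numbers of calls and do not test any single probe set, such as that of F47D12.6. For lists of that comparison 49 of 100 splits called as many (real 10, highest other 19), and 10 of the 32 did (highest other 17). For the difference between genotype effects the real count of 0 probe sets fixed the outcome (100 of 100 splits), so nothing was tested, while the highest other, 1742, again points to a structure of the samples. The 3 others of these 100 that part every replicate number called at most 0 probe sets and 11 lists for that difference. The comparisons of 3 against 3 arrays have 10 splits, too few for a share under 0.05. Their real and highest other counts of probe sets were 2 and 0 for genotype at 4 µM (1 split as large), 1 and 2 for genotype at 20 µM (2 splits), 8 and 0 for heme in wildtype (1 split) and 9 and 0 for heme in the mutant (1 split). The split giving 2 set wildtype replicate 1 and mutant replicates 1 and 2 against the rest. For lists the real and highest other counts were 3 and 14 for genotype at 4 µM (10 splits as large), 7 and 14 at 20 µM (7 splits), 5 and 17 for heme in wildtype (6 splits) and 7 and 13 in the mutant (9 splits). In each of these comparisons 3 other splits part every replicate number, and the rest put arrays of the same number together. Those 3 called at most 0 probe sets in each comparison, and at most 11 lists for genotype at 4 µM, 11 at 20 µM, 4 for heme in wildtype and 11 in the mutant.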

How the results depend on the processing

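Of the alternatives below, the fit on the arrays numbered 1 and 2 alone was chosen only after the data were seen. Signal near the floor limits the folds of the probe sets with the largest falls, and 3 arrays a group limit every call. F47D12.6 kept its call in every alternative that tested it. Centring, repeated quantile normalization, the trended robust prior and the added fold of 1.5 kept every count of probe sets within 1.5 times. The cause of the changes below was not tested unless stated.

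Keeping probe sets above the median mean called 0 for genotype at 4 µM, 0 at 20 µM and 0 averaged, since it leaves out F47D12.6 and 185275_at, and 5 for heme in wildtype. No moderation called 4 for genotype at 4 µM, 1 averaged, 3 for heme in wildtype and 4 in the mutant. Array weights called 67 for genotype at 20 µM (35 higher, 32 lower), 871 averaged, 1 for the difference of genotype effects, 15 for heme in wildtype and 1004 in the mutant. The 2 groups alone called 1 for genotype at 4 µM, 2 for heme in wildtype and 3 in the mutant, with fewer arrays for the spread. The replicate block called 15 and 18 for heme in wildtype and in the mutant, and 5 lists for genotype at 4 µM. The calls of lists and counts adjusted over the list alone that the block changed stand with each comparison. Numbers 1 and 2 alone called 2922, 275, 2996, 55 and 3167 for genotype at 4 µM, 20 µM and averaged and heme in wildtype and mutant, and 11, 11, 8 and 11 lists for genotype at 4 and 20 µM, their difference and heme in the mutant. On all arrays an estimated correlation and fry each called 0 lists in the 4 genotype comparisons and 1 in each heme comparison. Median centring called 7 lists for genotype at 4 µM.

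With 1 array left out, probe sets called ranged from 2 to 5 for genotype at 4 µM (lists 3 to 10), 1 to 1 at 20 µM (6 to 10), 1 to 3 averaged (6 to 12), 0 to 0 for the difference (2 to 8), 3 to 5 for heme in wildtype (6 to 13) and 3 to 49 in the mutant (4 to 10). Of the 36 list calls, 11 stood in every such fit, 25 ended in at least 1 and 5 turned direction in at least 1. The correlation of genotype effects ranged from -0.000459 to 0.606.

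Of results for single genes under the alternatives, 3846 kept direction and side, 169 newly passed (98 with numbers 1 and 2 alone, 62 with array weights), 88 no longer passed and 57 changed sign, none of these called. After centring mrp-5 and hrg-4 at 4 µM were 0.05 and 0.04, hrg-7 in the difference -0.13 and 185275_at for heme in the mutant -0.08. With array weights mrp-5 was 0.07, 0.02 and 0.05 at 4 µM, 20 µM and averaged, hrg-4 at 4 µM 0.04, hrg-3 at 20 µM 0, hrg-9 averaged 0.24, hrg-7 in the difference -0.24 and 185275_at in the mutant -0.02. With numbers 1 and 2 alone mrp-5 was 0.22, 0.09 and 0.15, hrg-4 at 4 µM 0.06, hrg-9 averaged 0.41, and hrg-7, hrg-10 and spe-40 in the difference -0.31, -0.16 and -0.12. With 1 array left out the ranges at 4 µM were 0 to 0.36 (hrg-7), -0.29 to 0.18 (mrp-5), -0.58 to 0.13 (hrg-1), -0.09 to 0.54 (hrg-9) and -0.42 to 0.38 (hrg-4). At 20 µM they were -0.03 to 0.24 (hrg-7), -0.37 to 0.19 (mrp-5), -0.15 to 0.68 (hrg-1) and -0.19 to 0.24 (hrg-3). Averaged they were -0.23 to 0.06 (mrp-5), -0.18 to 0.23 (hrg-1) and -0.25 to 0.07 (hrg-9). In the difference they were -0.23 to 0.13 (hrg-7), -0.33 to 0.28 (mrp-5) and -0.06 to 0.31 (hrg-10), and for 185275_at in the mutant -0.18 to 0.23.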

Other observations

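The comparison of the arrays numbered 3 with numbers 1 and 2 within groups was chosen only after the data were seen, and the genes below are from the 25 largest differences in each direction.

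Genes of sperm and its maturation were among the largest differences on the arrays numbered 3. By limma, ssp-10 was higher by 4.60 ± 0.41 log2 units (adjusted p 4.46e-05), ssp-34 by 4.34 ± 0.33 (2.5e-05), sss-1 by 4.52 ± 0.52 (0.000125) and spch-1, a sperm chromatin protein, by 4.36 ± 0.43 (6.34e-05). The sperm list was higher in 70 of 72 genes, 60 of them by more than 1 log2 unit, and in each group, with medians of 2.48 and 2.15 in wildtype and 4.21 and 1.98 in the mutant at 4 and 20 µM. All 24 oocyte and eggshell genes and 22 of 25 germ line genes were also higher. Of 145 cuticle collagens 115 were higher, 38 of them by more than 1 log2 unit: col-60 was higher by 4.53 ± 0.34 (2.44e-05) and col-106 by 4.32 ± 0.41 (5.66e-05), while col-41 was lower (-3.42 ± 0.47, 0.000358), and the list median was 0.38, -0.12, 0.33 and 1.20 in wildtype at 4 µM, mutant at 4 µM, wildtype at 20 µM and mutant at 20 µM.

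Genes lower on the arrays numbered 3 included pud-3 (-4.13 ± 0.50, adjusted p 0.000177), pud-4 (-3.89 ± 0.33, 3.66e-05), grl-6 (-3.34 ± 0.41, 0.000184), the aquaporin gene aqp-8 (-2.63 ± 0.31, 0.000152) and the glutathione S-transferase gst-41 (-2.70 ± 0.37, 0.000352) by limma. Of 45 glutathione S-transferases 3 were higher, and of 64 UDP-glucuronosyltransferases 10, with list medians of -0.60 and -0.67. The heme trafficking list had a median of -0.50, with 1 of 7 genes higher.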
